A study of Mus musculus with 90 samples.

How the data were processed

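The series holds RNA sequencing of 90 mouse T cell libraries in 30 groups. Per the labels, 60 libraries are CD8 T cells sorted from tumours into 4 populations by PD-1 and TIM-3, or taken from a non-draining lymph node. Their genotypes are written yfp, Il10, Ebi3L and DKO, and the series' design text describes knockouts of IL-10, of IL-35 and of both, made in regulatory T cells (Tregs). The other 30 libraries are Tregs sorted by expression of IL-10 and of Ebi3, a subunit of IL-35, from naive mice, non-draining lymph nodes (ndLN) or tumours (TIL), with naive effector T cells (Teff). Cells were sorted in 2 rounds, per the labels' protocols, with SMART-Seq cDNA synthesis (v4 for Tregs, v3 for CD8 cells) and Nextera XT libraries.

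The deposited count table holds whole-number read counts for 23420 genes. The reads were aligned with STAR and counted with featureCounts from the Subread package on mm10, per the submitters' processing notes. Versions, the gene annotation and the strand setting are not given in the sources used here, so genes that overlap on opposite strands cannot be told apart. The authors also deposited 2 tables of filtered log2 values. In the Treg table of 9885 genes each deposited log2 value equalled the log2 of the count plus 0.5, scaled to the library total as in CPM, plus a constant for the gene and batch. The within-batch SD of the remainder had a median of 0.00053. The CD8 table of 10150 genes matched the same formula after quantile normalisation, with a median within-batch SD of 2.9e-15. limma is also named in the submitters' processing notes. The counts served every main result, and the deposited log2 values served one alternative. Every column of the tables used here belonged to a sample of the series, and 0 columns were of no sample.

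Groups were taken from the titles and characteristics. Each Treg group had 3 libraries, and the replicate number of a Treg library is also its batch in the labels. For each CD8 population there were 3 yfp, 4 DKO, 2 Il10 and 3 Ebi3L libraries from 12 sources, a source being one genotype within one set of libraries. The set names come from the deposited descriptions, and CD8 replicate numbers only name samples. Nothing in the labels says that libraries came from separate animals, so p-values measure the spread between these samples, which may be partly technical. The yfp libraries lay in batches 1 and 3, DKO in 1 and 2, Il10 in 1 and 2 and Ebi3L in 1 and 3, so genotype and batch were only partly separable.

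Library totals ran from 9.73 to 47.7 M counts, with a median of 23.5 M. They ran from 19.2 to 47.7 M in the CD8 libraries and from 9.73 to 20.2 M in the Treg series. Between 10400 and 14363 genes had a count, and the 10 most abundant genes took 4.65 to 10.7% of a library. A gene at 0 in a library may lie below 0.0629 to 0.308 CPM, the level of 3 counts. Reads were amplified and carried no molecular identifiers, so floors cover counting error only. A chi-square comparison of the 95 pairs of libraries within groups, over genes with at least 20 summed counts, gave 34.7 to 651 per gene, and 0 pairs lay within sampling noise.

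Tests used edgeR 4.0.16 in R 4.3.3. Counts were scaled by TMM, genes were filtered by filterByExpr on the groups, and the quasi-likelihood test was fitted robustly. The Benjamini-Hochberg threshold was 0.05 in each of the 39 comparisons. Treg comparisons used all 30 Treg-series libraries with batch as a block of 3 levels. Comparisons among CD8 populations used the 15 yfp libraries with batch as a term. Genotype comparisons used the 12 libraries of a population with batch as a term. The differences of DP against NEG between genotypes used the 24 libraries of both populations with the source as a block. Log2 fold changes are given with their standard error (SE), and levels as mean CPM with SD. CPM is a count scaled to the library total, without TMM.

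Batch pairs the Treg libraries because the labels say that the number is a batch. Same-batch pairs of Treg libraries from different groups had a median correlation of deviations of 0.09 over 135 pairs, with a lowest of 0.01. Pairs from different batches had a median of -0.08 over 270 pairs, with a highest of 0.08. In the yfp CD8 libraries the median was 0.2 over 30 pairs of the same set, of which 26 lay above 0.1, and -0.14 over 60 other pairs. The set as replicate block was an alternative there.

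Altogether 26 gene lists were fixed before the data were examined. They cover inhibitory receptors, exhaustion regulators, memory and stem-like genes, cytotoxic effector genes, proliferation, type I interferon response, cytokine receptors and STAT3 targets, immediate early AP-1 genes, NF-kB and TNFR family, chemokine receptors and trafficking, glycolysis, oxidative phosphorylation, cholesterol synthesis, core Treg, effector Treg and resting Treg genes, suppressive mediators and helper lineage genes. Marker lists cover B cell, myeloid, NK cell, CD4 T cell, CD8 T cell, erythroid and platelet, stromal and pigment cell tumour markers. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison. The p with an estimated correlation, and fry, were computed beside it. The list p-values printed in the report are from the preset unless the sentence says otherwise. Some genes belong to more than one list, and some members are not reported here by name. Several list names use current symbols, and Cd244a, Vsir and Izumo1r were matched to Cd244, 4632428N05Rik and Folr4.

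Named genes follow a rule made before the data were examined. Among genes past adjusted p of 0.05, with libraries of both groups not overlapping on batch-adjusted log2 CPM and a higher group mean of at least 5 CPM, the 10 largest log2 fold changes per direction were taken. Predicted genes, pseudogenes, immunoglobulin and receptor segments, and ribosomal and mitochondrial genes were left out, and differences of differences had no overlap condition. Among 3 against 3 libraries chance gives no overlap for 10% of genes. Any member of a list may also be named, as may Il10, Ebi3, Il12a and Foxp3 in Tregs and Pdcd1 and Havcr2 in CD8 cells as checks of the sorts. Where a group had no counts, the fold was computed against 3 counts summed over the group and is written as at least that fold.

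Simulated counts with 50 genes changed at each of 4 fold sizes were used to test the same steps. For tumour IL10 against Ebi3 Tregs, 54% of genes changed by 2-fold and 66% of those changed by 4-fold were recovered among 12453 genes. For DKO against yfp in the DP population these shares were 20 and 50% among 12382 genes, and for Il10 against yfp in NEG 4 and 44% among 12003 genes. Alternatives were the fit without the batch block or with the set as block, DESeq2 1.42.0, its size factors in edgeR, no filter on low counts and each replicate left out. Alternatives added after seeing the data were limma on the deposited log2 values, fits without batch 3, without set 8, without the ndLN Ebi3 library high in Lyz2 or without the NEG Il10 library of fewest detected genes, and sums of the 5 CD8 populations per source. Targeted genes were compared across sources by two-sided exact permutation tests on log2(CPM + 1), with Benjamini-Hochberg adjustment over 5 populations for each gene. These tests were chosen after the values were seen, and they exchange sources across batches. Comparisons of Treg libraries with CD8 libraries cross 2 kit versions and are given as levels only, apart from one bound on Tregs in a CD8 sort.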

Results

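RNA sequencing was reported for 90 libraries of mouse T cells. The Treg series of 30 libraries held double-negative (DN), IL10-expressing and Ebi3-expressing Tregs from naive mice, from non-draining lymph nodes and from tumours, with naive effector T cells, at 3 libraries in each of 10 groups. The CD8 series of 60 libraries held tumour CD8 T cells that were PD-1 and TIM-3 negative (NEG), PD-1 intermediate and TIM-3 negative (INT), PD-1 high and TIM-3 negative (SP) or PD-1 high and TIM-3 positive (DP), and non-draining lymph node CD8 T cells (NDLN). Each of these 5 populations came from 3 yfp, 4 DKO, 2 Il10 and 3 Ebi3L libraries. Library totals were 9.73 to 20.2 M counts in the Treg series, with a median of 15.1 M, and 19.2 to 47.7 M in the CD8 series, with a median of 26.2 M. Below, changes are log2 fold changes ± SE from edgeR, a gene rose or fell where its adjusted p passed 0.05, and Treg and yfp groups have n = 3.

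The sorts were checked on the genes that defined them. Il10 averaged 131 ± 21.5 CPM (SD, n = 3) in tumour IL10 Tregs, 103 ± 14.8 in lymph node IL10 Tregs and 97.9 ± 27.1 in naive IL10 Tregs. It averaged 2.28 ± 1.01 CPM in tumour DN Tregs, 1.34 ± 0.499 in tumour Ebi3 Tregs, 2.36 ± 2.60 in lymph node Ebi3 Tregs, and 0.0817 and 0.0858 CPM in lymph node and naive DN Tregs. Ebi3, the subunit that IL-35 shares with IL-27, averaged 9.91 ± 5.10, 7.47 ± 2.87 and 8.34 ± 1.25 CPM in tumour, lymph node and naive Ebi3 Tregs. In the other Treg groups Ebi3 averaged at most 2.66 ± 3.55 CPM, in tumour IL10 Tregs. Il12a, which encodes the other IL-35 subunit, was near the detection floor, with 0.289 CPM in tumour Ebi3 Tregs and 0.0884 in tumour IL10 Tregs. Foxp3, the transcription factor of the Treg lineage, averaged 45.9 to 93.2 CPM in the Treg groups and 24.4 ± 7.41 in Teff. Summed myeloid markers, which include the MHC class II genes, were 917 ± 152, 1070 ± 218 and 1080 ± 245 CPM in tumour DN, IL10 and Ebi3 Tregs, and 344 ± 99.8, 710 ± 58 and 879 ± 243 in the lymph node groups. Lyz2, a macrophage gene, stood at 190 CPM in 1 lymph node Ebi3 library and at 1.53 CPM in the lowest of that group.

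**Figure D1:**
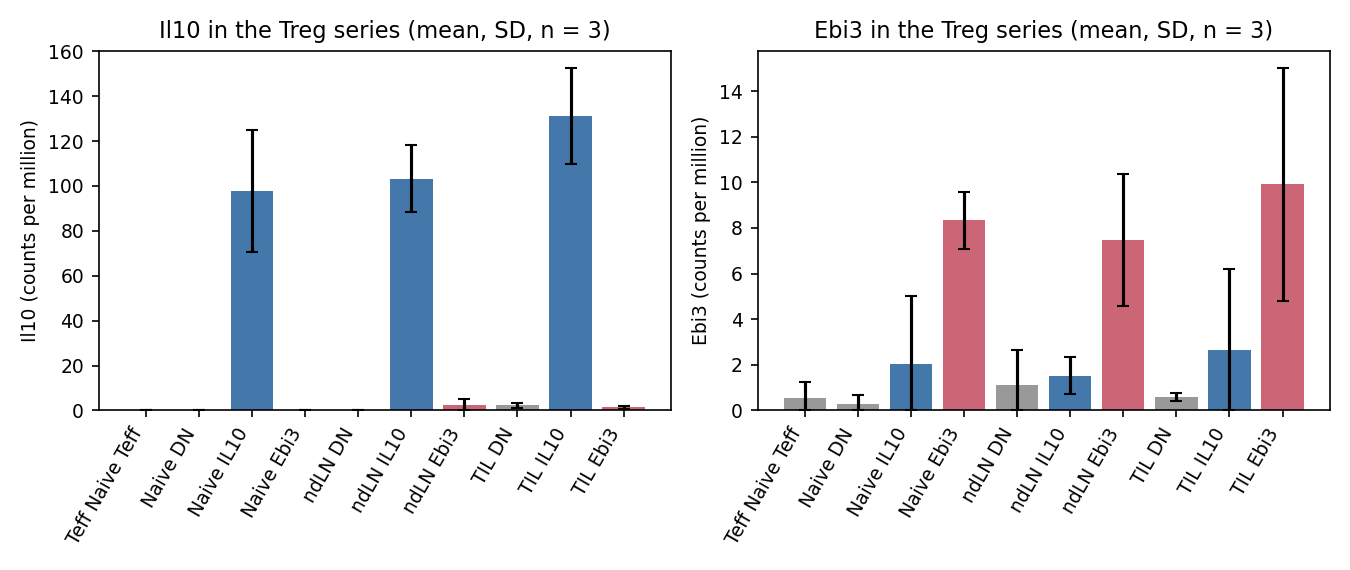
Mean level of Il10 and Ebi3 in CPM, linear axes from 0, in the 10 groups of the Treg series, with bars for the mean and error bars for the SD of 3 libraries. Il10 averaged 131 CPM in tumour IL10 Tregs against 2.28 in tumour DN Tregs.

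Naive DN Tregs carried the Treg programme when set against naive Teff. All 15 measured genes of the core Treg list rose (adjusted p = 7.63e-45). Il2ra, the IL-2 receptor alpha chain, stood at 7.85 ± 0.34, Ikzf2, which encodes Helios, at 5.89 ± 0.22, Ctla4 at 4.59 ± 0.21 and Foxp3 at 1.64 ± 0.27. In the effector Treg list 20 of 25 genes rose (adjusted p = 1.14e-29). Lrrc32, which presents latent TGF-beta, rose by 10.24 ± 0.40, Pla2g4f was at least 162-fold higher and Dusp14 at least 106-fold higher, while Pde3b fell by 4.23 ± 0.72 and Crtam was at least 259-fold lower. Among suppressive mediators 9 genes rose and 1 fell (adjusted p = 3.38e-14), and among inhibitory receptors 8 rose and 1 fell (adjusted p = 3.1e-11). Of the NF-kB and TNFR family 11 of 16 rose (13 adjusted over the list alone), and of the exhaustion regulators 9. Of the resting Treg list 6 genes fell and 1 rose, including Lef1 at -1.34 ± 0.13, and its adjusted p of 0.00098 became 0.0879 with an estimated correlation. In the proliferation list (adjusted p = 1.08e-09, and 0.151 with an estimated correlation) 6 genes rose, or 12 adjusted over the list alone. Cd79b and Cd74, which B cells express, rose by 5.45 ± 0.63 and 4.27 ± 0.37, with B cells in the sort untested. Of 12907 genes tested, 1134 rose and 441 fell. These 1575 calls became 1015, 1123 and 850 without batch 1, 2 or 3 and 857 without the batch block, and 8 of the 20 genes named by the rule passed in every leave-out fit.

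Tumour IL10 Tregs were compared with tumour DN Tregs to ask how IL-10 expression marks tumour Tregs. Il10 itself was higher by 5.97 ± 0.59 (adjusted p = 1.36e-06). Tcf7, which encodes TCF-1, fell by 2.69 ± 0.37, S1pr1, the receptor for lymph node egress, by 1.92 ± 0.18, Ccr7 by 1.88 ± 0.37 and Slamf6 by 0.77 ± 0.15. In the memory and stem-like list 6 of 18 genes fell and 1 rose, Cd27 at 0.48 ± 0.11 (adjusted p = 9.31e-10), with 9 falling when adjusted over the list alone. In the resting Treg list 4 of 16 fell, or 9 adjusted over the list alone (adjusted p = 2.74e-11). Of the effector Treg list 4 of 25 genes rose, or 8 adjusted over the list alone (adjusted p = 2.78e-07): Fgl2, a secreted suppressive protein, at 1.00 ± 0.18, Entpd1, the ectoenzyme CD39, at 0.87 ± 0.16, Itgae, the integrin CD103, at 0.83 ± 0.20 and Icos at 0.76 ± 0.14. Of the suppressive mediators 3 of 15 rose, or 6 adjusted over the list alone (adjusted p = 9.01e-06), while Nrp1 fell by 1.22 ± 0.27.

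Other single genes were also called in tumour IL10 against DN Tregs. Cd40lg fell by 2.15 ± 0.24, Tnfsf8, the CD30 ligand, by 4.25 ± 0.52, Itga4 by 1.43 ± 0.16, P2rx7, the ATP-gated channel, by 2.81 ± 0.36, Pdlim1 by 2.43 ± 0.27 and Cd160 by 2.41 ± 0.46, and Plagl1 was at least 151-fold lower. Sv2c, Arl5a and Sdc4 rose by 1.45 ± 0.24, 1.30 ± 0.22 and 1.13 ± 0.27, and Folr4 by 0.59 ± 0.10. The cytokine receptors and STAT3 targets list (adjusted p = 0.000237, and 0.157 with an estimated correlation), glycolysis (0.00373, and 0.164 with it), cholesterol synthesis (0.00838, and 0.246), oxidative phosphorylation (0.0121, and 0.508) and stromal markers (0.0261, and 0.0846) lost their calls with an estimated correlation. The core Treg list had an adjusted p of 0.0539, inhibitory receptors 0.182, proliferation 0.816, type I interferon response 0.151, immediate early AP-1 0.272, cytotoxic effector 0.305, helper lineage 0.459, chemokine receptors and trafficking 0.494, and myeloid, B cell, NK cell, pigment cell tumour, and erythroid and platelet markers 0.414, 0.816, 0.788, 0.459 and 0.694. In all 35 genes rose and 73 fell. The count of 108 became 43, 45 and 32 without batch 1, 2 or 3, 33 without the batch block, 221 with DESeq2 and 181 with limma on the deposited values. Of the 20 genes named by the rule 4 passed in every leave-out fit.

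In tumour Ebi3 Tregs, set against tumour DN Tregs, S1pr1 fell by 2.04 ± 0.19 (adjusted p = 3.65e-07), Klf2, a transcription factor that maintains S1pr1, by 2.40 ± 0.34, Tcf7 by 1.71 ± 0.35, Cd27 by 0.72 ± 0.11 and Cd40lg by 1.61 ± 0.23. Of the resting Treg list 6 of 16 genes fell and of the memory and stem-like list 5 of 18, and 9 of each when adjusted over the list alone (adjusted p = 7.58e-16 for both). The lists of chemokine receptors and trafficking (2 fell, adjusted p = 3.39e-05), CD8 T cell markers (Runx3 at -0.83 ± 0.20, adjusted p = 0.00101) and the NF-kB and TNFR family (1 fell, adjusted p = 0.000521) were lower. Of the effector Treg list only Nt5e, the ectoenzyme CD73, fell, at -1.31 ± 0.21, and the list had an adjusted p of 0.216. Pde2a, Cd7 and Socs3 fell by 2.43 ± 0.35, 2.00 ± 0.30 and 1.77 ± 0.40. Psat1 and Phgdh of serine synthesis rose by 0.88 ± 0.18 and 0.71 ± 0.16, Impdh2 of purine synthesis by 0.71 ± 0.15 and Cd81 by 0.63 ± 0.14. The proliferation list stood higher with 0 genes passing singly (adjusted p = 2.18e-07, and 0.252 with an estimated correlation), beside summed levels of 4710 ± 1450 CPM in tumour Ebi3 and 2620 ± 512 in tumour DN Tregs. Calls for immediate early AP-1 (0.0769), cytotoxic effector (0.0769), type I interferon response (0.395), inhibitory receptors (0.101), CD4 T cell markers (0.101), cytokine receptors and STAT3 targets (0.32), oxidative phosphorylation (0.356) and cholesterol synthesis (0.32) were lost at these adjusted p-values with an estimated correlation. Altogether 11 genes rose and 81 fell. The count of 92 became 17, 28 and 10 without batch 1, 2 or 3 and 16 without the batch block. DESeq2 gave 47 higher and 149 lower and limma on the deposited values 35 and 112, and 3 of the 19 genes named by the rule passed in every leave-out fit.

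Between the cytokine-defined tumour Tregs, IL10 cells carried more of the suppressive and effector genes than Ebi3 cells. Il10 was higher by 6.72 ± 0.61 (adjusted p = 4.26e-07), Lag3, an inhibitory receptor, by 2.54 ± 0.51, Nt5e by 1.37 ± 0.21, Itgae by 1.22 ± 0.20 and Ctla4 by 0.72 ± 0.17. Of the suppressive mediators 6 of 15 rose, or 11 adjusted over the list alone (adjusted p = 2.36e-07). Of the effector Treg list 7 of 25 rose, or 14 over the list alone (adjusted p = 1.03e-07), and of the inhibitory receptors 5 of 12 (adjusted p = 0.00205). The cytokine receptors and STAT3 targets rose in 4 of 15 cases (adjusted p = 2.08e-07), with Il6st at 1.89 ± 0.29 and Socs3 at 1.61 ± 0.40, and the NF-kB and TNFR family in 4 of 16 (adjusted p = 9.38e-05). Cd27 rose by 1.20 ± 0.11, Itgb8, which activates TGF-beta, by 1.82 ± 0.35 and Gcnt1 by 1.87 ± 0.38. Tnfsf8 fell by 3.82 ± 0.52, P2rx7 by 2.74 ± 0.36, Tnfsf11, which encodes RANKL, by 1.95 ± 0.34, Pdlim1 by 1.81 ± 0.27 and Lad1 by 4.65 ± 0.78. The oxidative phosphorylation list, with 2 genes that fell, had an adjusted p of 1.49e-06, or 0.153 with an estimated correlation, and proliferation 3.4e-06, or 0.273 with an estimated correlation. Core Treg and chemokine receptors and trafficking each stood at 0.0504 with an estimated correlation. In all 228 genes rose and 138 fell, against 322 and 315 with DESeq2 and 234 and 441 with limma on the deposited values. The count of 366 became 105, 121 and 32 without batch 1, 2 or 3 and 51 without the batch block, and 5 of the 20 genes named by the rule passed in every leave-out fit.

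In tumour against lymph node DN Tregs 23 of 25 effector Treg genes rose (adjusted p = 5.84e-23), with Fgl2 at 5.33 ± 0.22 and Tnfrsf9, which encodes 4-1BB, at 3.72 ± 0.26. In the resting Treg list 14 of 16 genes fell (adjusted p = 4.33e-16), with Tcf7 at -3.19 ± 0.35. Glycolysis rose in 14 of 17 genes (adjusted p = 6e-19), with Aldoa at 2.07 ± 0.08 and Tpi1 at 3.12 ± 0.15, and cholesterol synthesis in 13 of 16 (adjusted p = 4.22e-09), with Hmgcs1 at 1.73 ± 0.24. Of the cytotoxic effector list 13 of 18 rose (adjusted p = 1.39e-08), led by the chemokine gene Ccl3 at 10.15 ± 0.95. Of the NF-kB and TNFR family 10 of 16 rose (adjusted p = 5.36e-09) and of the exhaustion regulators 9 of 15 (adjusted p = 1.97e-07), with Id2 at 4.59 ± 0.23. Of the memory and stem-like list 14 of 18 fell, of the suppressive mediators 10 of 15 rose and of the inhibitory receptors 8 of 12 rose, with Pdcd1 at 2.55 ± 0.13. Msrb3, Galnt3, Perp and Pparg were at least 316-fold, 303-fold, 234-fold and 203-fold higher, Ampd1 was at least 260-fold lower, and Abca1 and Igfbp4 fell by 6.35 ± 0.61 and 6.28 ± 0.74. Genes of the type I interferon response rose in 15 of 22 cases (adjusted p = 2.74e-06, and 0.153 with an estimated correlation). Tumour cell and myeloid transcripts were measured beside these: Cd74 rose by 1.71 ± 0.31 and 4 of 12 myeloid markers rose (adjusted p = 0.00596), and the melanocyte gene Tyrp1 rose by 8.73 ± 1.90, while pigment cell tumour markers summed to 21.2 ± 8.77 CPM in tumour and 28.9 ± 6.45 in lymph node DN Tregs. In all 1662 genes rose and 1355 fell, against 1430 and 2114 with limma on the deposited values, which shifted the median of all genes by -0.11. The count of 3017 became 2242, 1836 and 1731 without batch 1, 2 or 3 and 1849 without the batch block.

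The site also separated IL10 Tregs. Tumour IL10 Tregs were higher than lymph node IL10 Tregs in 14 of 17 glycolysis genes (adjusted p = 1.51e-32), with the glucose transporter Slc2a1 at 2.52 ± 0.18. They were also higher in 13 of 16 cholesterol synthesis genes (adjusted p = 4.11e-19), with Sqle at 3.13 ± 0.36, and in 16 of 22 type I interferon response genes (adjusted p = 1.92e-15). The NF-kB and TNFR family had 10 of 16 genes that rose (adjusted p = 1.03e-07), immediate early AP-1 9 of 18 (adjusted p = 1.03e-07) and cytotoxic effector 8 of 18 (adjusted p = 3.05e-07), while 9 of 18 memory and stem-like genes fell (adjusted p = 4.33e-09). The effector Treg list moved both ways, with 10 genes that rose and 4 that fell (adjusted p = 0.00661, and 0.141 with an estimated correlation). Fgl2 rose by 1.56 ± 0.18, whereas Itgae fell by 2.32 ± 0.21 and Icos by 0.53 ± 0.14. Upp1 and Gda were at least 473-fold and 295-fold higher, and Aff3, Abca1, Tnfsf8, Dtx1 and Cxcr5 stood at -5.22 ± 0.52, -4.47 ± 0.54, -4.16 ± 0.52, -4.10 ± 0.64 and -4.71 ± 1.02. The lists of pigment cell tumour markers (0.145), B cell markers (0.159) and cytokine receptors and STAT3 targets (0.0531) lost their calls with an estimated correlation, at these adjusted p-values. In all 717 genes rose and 486 fell, whereas limma on the deposited values gave 546 and 1410 and a median of all genes shifted by -0.18. The count of 1203 became 701, 801 and 535 without batch 1, 2 or 3 and 643 without the batch block.

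Ebi3 Tregs differed between sites in many of these lists. The glycolysis list rose in 14 of 17 genes (adjusted p = 2.75e-29), cholesterol synthesis in 13 of 16 (adjusted p = 2.39e-20), type I interferon response in 16 of 22 (adjusted p = 5.94e-17) and cytotoxic effector in 10 of 18 (adjusted p = 1.85e-09). Of the resting Treg list 12 of 16 genes fell (adjusted p = 2.02e-14), and of the memory and stem-like list 14 of 18 (adjusted p = 2.25e-17). Of the effector Treg list 16 of 25 rose and 3 fell (adjusted p = 3.71e-10), with Fgl2 at 3.57 ± 0.20 and Itgae at -1.60 ± 0.20. Ccl4 and Ccl3 rose by 7.91 ± 1.24 and 6.98 ± 0.78, AA467197 by 9.85 ± 1.13, Mt2 by 7.88 ± 1.44 and Upp1 by 7.72 ± 1.16. Aff3, Abca1 and Wnt10a fell by 6.08 ± 0.48, 5.72 ± 0.58 and 5.79 ± 1.16. The B cell markers (0.139) and the cytokine receptors and STAT3 targets list (0.0726) lost their calls with an estimated correlation. In all 805 genes rose and 518 fell, against 619 and 1284 with limma on the deposited values, which shifted the median of all genes by -0.16. The count of 1323 became 887, 775 and 691 without batch 1, 2 or 3 and 753 without the batch block.

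In lymph node IL10 against DN Tregs, Il10 was higher by 10.11 ± 0.81, Itgae by 4.43 ± 0.23, Fgl2 by 4.78 ± 0.21 and Icos by 2.94 ± 0.15, and 23 of 25 effector Treg genes rose, or 25 adjusted over the list alone (adjusted p = 2.1e-32). Of the resting Treg list 14 of 16 fell (adjusted p = 7.04e-22), with Ly6c1 at -5.95 ± 0.34 and Satb1 at -2.86 ± 0.23, and of the memory and stem-like list 11 of 18 (adjusted p = 2.63e-10). Of the suppressive mediators 9 of 15 rose (adjusted p = 2.5e-09), and exhaustion regulators rose in 7 of 15 cases (adjusted p = 2.31e-07). The inhibitory receptors rose in 7 of 12 (adjusted p = 1.09e-05) and cytotoxic effector genes in 8 of 18 (adjusted p = 0.000747). Msrb3, Pparg and Fam83g were at least 180-fold, 165-fold and 138-fold higher, Lad1 and Scmh1 fell by 8.48 ± 0.97 and 6.05 ± 1.19, and Arhgap20 was at least 148-fold lower. The proliferation list, with 10 of 20 genes that rose, had an adjusted p of 2.22e-06, or 0.287 with an estimated correlation, and the calls of type I interferon response (0.415), glycolysis (0.174), NF-kB and TNFR family (0.0722), helper lineage (0.158) and myeloid markers (0.0722) were also lost with it. Summed stromal markers stood at 46 ± 1.52 CPM in lymph node IL10, 96 ± 8.69 in Ebi3 and 225 ± 54.4 in DN Tregs, and B cell markers at 80.3 ± 27, 87.1 ± 20.6 and 37.5 ± 19.5. Of 2088 called genes 1137 rose and 951 fell, and the count became 1430, 1146 and 1126 without batch 1, 2 or 3 and 1115 without the batch block.

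Lymph node Ebi3 Tregs also differed from DN Tregs. Of the effector Treg list 17 of 25 genes rose (adjusted p = 1.24e-13), with Itgae at 2.49 ± 0.21, Fgl2 at 2.07 ± 0.20 and Icos at 1.80 ± 0.15, and 11 of 16 resting Treg genes fell (adjusted p = 7.47e-14), led by Ly6c1 at -5.37 ± 0.32. In the proliferation list 16 of 20 genes rose, and all 20 when adjusted over the list alone (adjusted p = 7.47e-14, and 0.124 with an estimated correlation), beside summed levels of 5430 ± 830 CPM against 1270 ± 356 in lymph node DN Tregs. Exhaustion regulators rose in 9 of 15 genes (adjusted p = 0.000292) and memory and stem-like genes fell in 9 of 18 (adjusted p = 5.75e-07). Mlf1 and Zfand4 rose by 5.18 ± 0.81 and 4.50 ± 0.91 and Mocos was at least 81.7-fold higher, while Itih5, Ampd1, Igfbp4 and Atp1b1 fell by 4.01 ± 0.41, 4.46 ± 0.84, 3.40 ± 0.62 and 3.39 ± 0.46. Calls of type I interferon response (0.22), cytokine receptors and STAT3 targets (0.156), suppressive mediators (0.11), glycolysis (0.22), oxidative phosphorylation (0.407) and immediate early AP-1 (0.22) were lost with an estimated correlation. Of 1681 called genes 898 rose and 783 fell, with 1029, 874 and 765 called without batch 1, 2 or 3, 762 without the batch block and 1060 without the Ebi3 library high in Lyz2.

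Between IL10 and Ebi3 Tregs of the lymph node, 18 of 25 effector Treg genes (adjusted p = 1.09e-22) and 8 of 15 suppressive mediators (adjusted p = 1e-11) were higher in IL10 cells, with Il10 at 5.60 ± 0.58, Plek at 4.22 ± 0.62, Lag3 at 3.97 ± 0.55 and Fgl2 at 2.71 ± 0.19. The inhibitory receptors rose in 8 of 12 cases (adjusted p = 2.73e-07), cytotoxic effector in 8 of 18 (adjusted p = 9.89e-06) and core Treg in 6 of 15 (adjusted p = 5.46e-05), and resting Treg genes fell in 7 of 16 (adjusted p = 7.66e-10). Lad1, Wnt10a, Capn3 and Dzip1 fell by 7.21 ± 0.95, 6.11 ± 1.18, 3.51 ± 0.38 and 3.50 ± 0.63. Proliferation (0.428), type I interferon response (0.566) and stromal markers (0.0519) lost their calls with an estimated correlation. The 404 genes that rose and 250 that fell compare with 390 and 455 by limma on the deposited values. The count of 654 became 450, 323 and 178 without batch 1, 2 or 3, 250 without the batch block and 351 without the Ebi3 library high in Lyz2.

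In naive IL10 Tregs all 25 effector Treg genes rose against DN Tregs (adjusted p = 4.87e-38), with Fgl2 at 5.86 ± 0.23 and Icos at 3.57 ± 0.16, and 14 of 16 resting Treg genes fell (adjusted p = 3.28e-20), with Satb1 at -5.42 ± 0.27. The suppressive mediators (10 rose, adjusted p = 3.38e-10), exhaustion regulators (8 rose, adjusted p = 5.68e-08) and inhibitory receptors (7 rose, adjusted p = 3.21e-06) were higher. Ltb4r1, Pparg and Gpr55 were at least 701-fold, 306-fold and 288-fold higher, Cnn3 was at least 961-fold lower and Ampd1 fell by 9.13 ± 1.20. The proliferation list (12 rose, adjusted p = 1.68e-06) and the type I interferon response list (9 fell, adjusted p = 0.000362) had adjusted p of 0.227 and 0.265 with an estimated correlation. Summed myeloid markers stood at 302 ± 91.1 CPM in naive DN, 635 ± 51.9 in IL10 and 822 ± 159 in Ebi3 Tregs, and stromal markers at 206 ± 65.3, 49.5 ± 14.7 and 110 ± 18.1. Of 2301 called genes 1288 rose and 1013 fell, and the count was 1550, 1495 and 1241 without batch 1, 2 or 3 and 1374 without the batch block.

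In naive Ebi3 Tregs, all 20 proliferation genes rose against DN Tregs (adjusted p = 1.51e-17, and 0.0672 with an estimated correlation), with Mki67 at 3.27 ± 0.67 and E2f7 at 8.56 ± 1.01, and Espl1 was at least 321-fold higher. Of the effector Treg list 18 of 25 rose (adjusted p = 2.53e-18) and of the resting Treg list 11 of 16 fell (adjusted p = 4.31e-15), with Ly6c1 at -5.29 ± 0.33. The 955 genes that rose and 703 that fell make 1658, and 1060, 934 and 796 were called without batch 1, 2 or 3 and 899 without the batch block. Naive IL10 Tregs were higher than naive Ebi3 Tregs in 19 of 25 effector Treg genes (adjusted p = 2.7e-28) and 10 of 15 suppressive mediators (adjusted p = 2.65e-13), with Il10 at 9.62 ± 0.79. Gzmb rose by 4.91 ± 0.75 and Havcr2 by 4.25 ± 0.78, while Lad1 fell by 7.30 ± 0.95. The 425 genes that rose and 282 that fell compare with 399 and 591 by limma on the deposited values, and the count of 707 became 498, 290 and 278 without batch 1, 2 or 3 and 322 without the batch block.

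The difference between IL10 and DN Tregs was itself tested between tumour and lymph node. It was smaller in the tumour for 18 of 25 effector Treg genes, or 24 adjusted over the list alone (adjusted p = 2.36e-28): Itgae at -3.61 ± 0.29, Fgl2 at -3.77 ± 0.27, Icos at -2.18 ± 0.20, Maf at -2.98 ± 0.45 and Prdm1, which encodes Blimp-1, at -2.80 ± 0.46. Outside that list Tnfrsf1b, a TNF receptor, was lower at -1.97 ± 0.21 and Id2 at -1.89 ± 0.28. Of the resting Treg list 6 of 16 genes, or 10 adjusted over the list alone, had a difference above that of the lymph node (adjusted p = 3.19e-12), with Ly6c1 at 5.28 ± 0.41 and Satb1 at 3.09 ± 0.31. Fgl2 averaged 8.25 CPM in lymph node DN and 222 in lymph node IL10 Tregs, but 296 in tumour DN and 567 in tumour IL10 Tregs. The exhaustion regulators (7 lower, adjusted p = 5.78e-08), suppressive mediators (7 lower, 1 higher, adjusted p = 2.8e-06) and inhibitory receptors (4 lower, adjusted p = 5.78e-06) were lower. So were CD8 T cell markers, a list that holds Itgae (2 lower, adjusted p = 0.000765). The memory and stem-like list was higher (6 higher, 2 lower, adjusted p = 0.000199). Proliferation (0.283), NF-kB and TNFR family (0.0614), helper lineage (0.0614), cytokine receptors and STAT3 targets (0.397) and oxidative phosphorylation (0.506) lost their calls with an estimated correlation. Of 579 called genes 256 were higher and 323 lower, and the count was 338, 211 and 212 without batch 1, 2 or 3, 170 without the batch block and 906 with DESeq2. Of the 20 genes named by the rule 3 passed in every leave-out fit.

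For Ebi3 against DN 208 genes passed the test of the site difference, 83 higher and 125 lower in the tumour. Itgae was lower by the site difference of -2.88 ± 0.29, Icos of -1.84 ± 0.20, Fgl2 of -1.77 ± 0.27, Cd40lg of -2.08 ± 0.32 and Slamf6 of -1.39 ± 0.21, and 9 of 25 effector Treg genes were lower, or 16 adjusted over the list alone (adjusted p = 5.47e-19). Ly6c1 at 4.18 ± 0.41 and Itga4 at 1.48 ± 0.22 were higher. The exhaustion regulators (4 lower, adjusted p = 1.44e-05), suppressive mediators (3 lower, adjusted p = 0.00163) and the NF-kB and TNFR family (3 lower, adjusted p = 0.00197) held with an estimated correlation, and resting Treg genes (0.172), proliferation (0.255), inhibitory receptors (0.122) and type I interferon response (0.406) did not. For IL10 against Ebi3 the site changed 23 genes, 16 higher and 7 lower, among them Fgl2 at -2.01 ± 0.25, Asap1 at 2.46 ± 0.24, Themis, a T cell receptor signalling gene, at 2.42 ± 0.35 and Gpr18 at 1.84 ± 0.23. The lists of resting Treg (1 higher, 9 adjusted over the list alone, adjusted p = 6.15e-14), effector Treg (1 lower, 5 adjusted over the list alone, adjusted p = 8.4e-10) and memory and stem-like genes (adjusted p = 1.6e-09) differed, and DESeq2 gave 48 genes higher and 36 lower. The count of 208 became 102, 52 and 52 without batch 1, 2 or 3, 40 without the batch block, 129 without the Ebi3 library high in Lyz2 and 404 with DESeq2. The count of 23 became 12, 10 and 7, and 7 and 15 without the batch block and without that library.

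**Figure D2:**
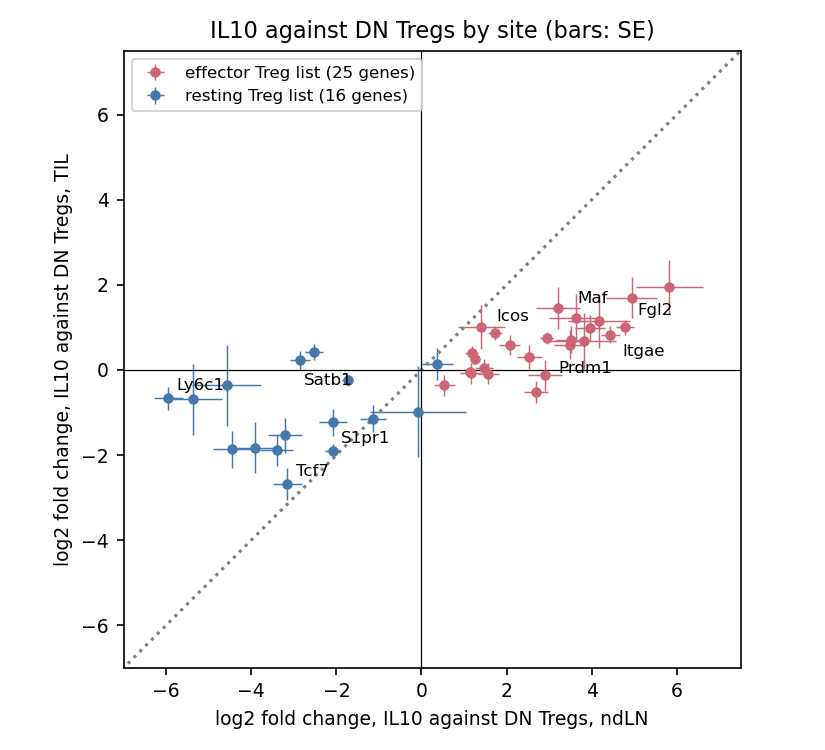
Log2 fold change of IL10 against DN Tregs in the lymph node (x axis) and in the tumour (y axis) for the 25 effector Treg and 16 resting Treg genes, with SE bars, 3 libraries per group and a dotted line of equality. Fgl2 sits at 4.78 and 1.00, and Itgae at 4.43 and 0.83.

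The CD8 series asked how loss of IL-10, of IL-35 or of both from Tregs changed CD8 T cells, so the targeted genes were read first in the CD8 libraries themselves. Ebi3 was lower in the CD8 cells of both genotypes that target it. It averaged 17.5 ± 5.96 CPM in yfp SP cells (SD, n = 3) and 20.3 ± 24.6 in Il10 SP cells (n = 2), against 0.659 ± 0.615 in DKO SP cells (n = 4) and 0.739 ± 0.831 in Ebi3L SP cells (n = 3). In DP cells it averaged 2.29 ± 0.104 CPM in yfp, 11.7 ± 7.57 in Il10, 0.252 ± 0.224 in DKO and 0.0599 in Ebi3L. In the same order it averaged in INT cells 5.83 ± 9.21, 3.42 ± 3.30, 0.0398 and 0.065, in NEG cells 0.311, 0, 0.128 and 0, and in NDLN cells 0.514, 0, 0.155 and 0. Over sources, the 7 that target Ebi3 lay at 0 to 0.508 CPM in DP and 0 to 1.64 in SP, and the 5 others at 2.17 to 17 and 2.96 to 37.7. Two-sided exact permutation tests gave p = 0.0013 for DP and for SP, the smallest that 792 arrangements can give with these values (adjusted p = 0.0032), p = 0.01 for INT (adjusted p = 0.017) and p = 0.73 for NEG and for NDLN. In libraries sharing set and batch label, Ebi3 was lower where it is targeted in 12 of 12 pairs of DP, SP and INT cells, from 4 pairs of sources, and in 2 of 3 pairs of set 12, whose batch labels differ. No edgeR test of Ebi3 passed over all genes, with -5.43 ± 1.24 in DKO SP cells (adjusted p = 0.391) and -4.74 ± 1.27 in Ebi3L SP cells (adjusted p = 0.684). Counts per gene do not tell a deletion in the CD8 cells from another source of the transcript.

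**Figure D3:**
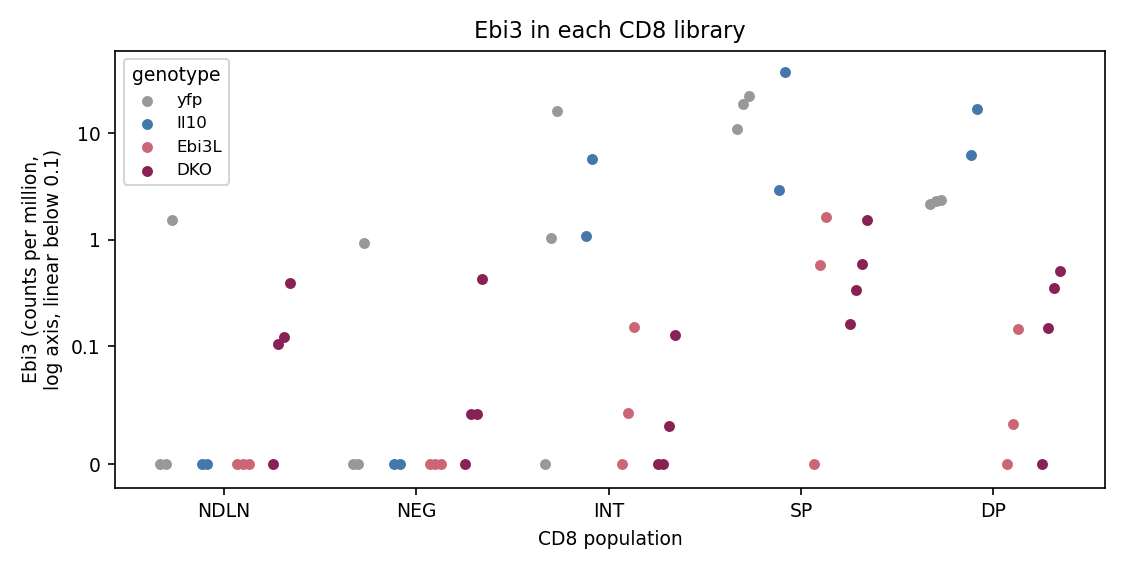
Ebi3 level in CPM in each of the 60 CD8 libraries, by population and genotype, on an axis that is linear below 0.1 CPM and logarithmic above. The 7 libraries of Ebi3L and DKO sit at 0 to 1.64 CPM in SP cells, below the 5 yfp and Il10 libraries at 2.96 to 37.7.

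No test of Il10 between the genotypes passed in CD8 cells. It averaged 4.25 ± 3.59 CPM in yfp DP, 0.676 ± 0.25 in Il10 DP, 14.6 ± 26 in DKO DP and 12.1 ± 14.8 in Ebi3L DP cells. SP cells averaged 1.03, 0.623, 1.38 and 3.53 CPM in the same order, INT cells 0.294, 0, 0.855 and 0.634, NEG cells 0.136, 0, 0.0759 and 0.51, and NDLN cells 0 in each genotype. The 6 sources that target Il10 lay at 0.102 to 53.4 CPM in DP cells and the 6 others at 0 to 28.6, with exact permutation p = 0.56 in DP, 0.59 in SP, 0.99 in INT and 0.45 in NEG. The sort genes followed the gates. Havcr2, which encodes TIM-3, averaged 299 ± 97.8 CPM in yfp DP, 62.1 ± 25.8 in SP, 14.6 in INT, 0.0493 in NEG and 0 in NDLN cells, and in DP cells 295 ± 86.8 in DKO, 274 ± 10.4 in Il10 and 282 ± 166 in Ebi3L. Pdcd1, which encodes PD-1, averaged 1130 ± 370 CPM in yfp DP, 1275 in SP, 483 in INT, 20.8 in NEG and 11.1 in NDLN cells, and 1569 ± 230 in DKO, 1272 in Il10 and 1112 ± 462 in Ebi3L DP cells. Summed myeloid markers were 397 ± 222 CPM in yfp, 546 ± 334 in DKO, 465 ± 317 in Il10 and 887 ± 245 in Ebi3L DP cells. Ebi3L and yfp cells stood at 1280 ± 648 and 522 ± 241 in SP and at 518 ± 403 and 210 ± 113 in INT. These unadjusted sums do not tell genotype from batch.

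The yfp libraries were compared along the PD-1 and TIM-3 gates, with 12791 genes tested. From lymph node to tumour NEG cells immediate early AP-1 genes rose in 6 of 18 cases, or 13 adjusted over the list alone (adjusted p = 4.15e-10, and 0.0225 with an estimated correlation), with Junb at 2.18 ± 0.36 and Fosb at 4.52 ± 0.78. Cytokine receptors and STAT3 targets rose in 5 of 15 (adjusted p = 1.6e-07), with Il12rb2, an IL-12 receptor chain, at 3.61 ± 0.49 and Pim1 at 2.85 ± 0.52. Of the exhaustion regulators 4 of 15 rose (adjusted p = 3.96e-06), with Nr4a2 at 2.15 ± 0.38, and of the helper lineage genes 2 of 12 (adjusted p = 0.000192), Tbx21 at 2.30 ± 0.43 and Rora at 2.15 ± 0.47. NK cell markers rose in 3 of 5 (adjusted p = 5.44e-07), with Klrk1, the receptor NKG2D, at 2.61 ± 0.49, and their sum went from 123 ± 20.7 CPM in NDLN to 387 ± 203 in NEG cells. Of the cytotoxic effector list 4 of 20 rose, or 10 adjusted over the list alone, with Fasl at 3.55 ± 0.62 and Ccl5 at 2.74 ± 0.57, and of glycolysis 6 of 18, with Tpi1 at 1.91 ± 0.19. These lists had adjusted p of 0.0502 and 0.0623 with an estimated correlation, and NF-kB and TNFR family 0.0821, effector Treg 0.134, type I interferon response 0.333, cholesterol synthesis 0.298 and proliferation 0.562. Tnfaip3, a brake on NF-kB, rose by 2.79 ± 0.29 and Pdgfb by 7.86 ± 0.69. Metrnl, Cd244 and Klrg1 were at least 450-fold, 258-fold and 135-fold higher, Wnt10a was at least 232-fold lower and Tspan32 fell by 1.74 ± 0.32. In all 169 genes rose and 31 fell, against 520 and 186 with DESeq2 and 164 and 76 with limma on the deposited values. The count of 200 became 63, 763 and 26 without replicate 1, 2 or 3 and 53 without the batch term, and 5 of the 20 genes named by the rule passed in every leave-out fit.

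INT cells differed from NEG cells in inhibitory receptors, of which 4 of 12 rose, or 5 adjusted over the list alone (adjusted p = 1.8e-07, and 0.0434 with an estimated correlation). Pdcd1 rose by 4.49 ± 0.83, Lag3 by 4.50 ± 0.90 and Ctla4 by 2.41 ± 0.44. The effector Treg list, which activated T cells share, had 5 of 24 genes that rose (adjusted p = 2.74e-11), with the chemokine receptor Ccr8 at 4.01 ± 0.68. The suppressive mediators (2 rose, adjusted p = 8.42e-06), exhaustion regulators (2 rose, adjusted p = 8.28e-06), with Id2 at 1.45 ± 0.23, and core Treg genes (2 rose, adjusted p = 3.25e-05) were higher. The resting Treg list was lower with 0 genes passing singly and 7 falling when adjusted over the list alone (adjusted p = 1.94e-08). The memory and stem-like list was lost with an estimated correlation (adjusted p = 0.0539). Calls of cytotoxic effector (0.273), proliferation (0.447), type I interferon response (0.55), trafficking (0.273) and glycolysis (0.307) were lost likewise. Cxcr6 and Itga4, which serve tissue homing, rose by 1.64 ± 0.24 and 1.51 ± 0.23, Casp1 by 2.67 ± 0.41 and Ttc39c by 3.84 ± 0.42, and Plxdc2 was at least 162-fold higher, while Txk and Rras2 fell by 1.61 ± 0.18 and 1.68 ± 0.30. In all 75 genes rose and 45 fell. The count of 120 became 19, 9 and 1 without replicate 1, 2 or 3, 4 without the batch term, 545 with DESeq2 and 187 without the filter on low counts.

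SP cells differed from INT cells in exhaustion regulators, of which 4 of 15 rose, with Tox, a transcription factor of exhausted cells, at 1.83 ± 0.34, Nr4a2 at 2.06 ± 0.37 and Batf at 1.16 ± 0.24 (adjusted p = 0.0263, and 0.253 with an estimated correlation). Of the memory and stem-like list 5 of 18 fell (adjusted p = 4.03e-05, and 0.143), with Klf2 at -2.83 ± 0.61, Satb1 at -2.33 ± 0.48 and Foxp1 at -1.45 ± 0.20. Glycolysis rose in 7 of 18 genes (adjusted p = 1.54e-05, and 0.243), with Tpi1 at 1.14 ± 0.18 and Pfkl at 0.93 ± 0.13, and oxidative phosphorylation in 3 of 22 (adjusted p = 1.54e-05, and 0.256). Of the type I interferon response list 3 of 22 fell, or 12 adjusted over the list alone (adjusted p = 9.79e-10, and 0.281), with Irf7 at -1.11 ± 0.25. Each second value is the adjusted p with an estimated correlation, and no list kept its call with it. Ccr8 and Prf1, which encodes perforin, rose by 3.13 ± 0.62 and 1.14 ± 0.25 and Scin was at least 579-fold higher. Itgae, Socs3, Klra7 and Pde2a stood at -3.65 ± 0.75, -2.27 ± 0.55, -5.78 ± 0.91 and -4.68 ± 0.84, and Igfbp4 was at least 427-fold lower. In all 237 genes rose and 389 fell. The count of 626 became 131, 301 and 80 without replicate 1, 2 or 3, 9 without the batch term, 1018 with the set as replicate block and 1356 with DESeq2.

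DP cells were lower than SP cells in memory and stem-like genes. Tcf7 fell by 7.40 ± 0.56 (adjusted p = 0.000114), from 154 ± 42.9 to 0.905 ± 0.895 CPM. Id3 fell by 7.84 ± 0.89 and Slamf6 by 3.28 ± 0.46. Cxcr5, a chemokine receptor of follicular and stem-like cells, fell by 4.62 ± 0.80. Of this list 8 of 18 fell, or 15 adjusted over the list alone (adjusted p = 1.35e-28, and 0.000477 with an estimated correlation). Of the resting Treg list 5 of 16 fell (adjusted p = 3.61e-17), of chemokine receptors and trafficking 1 of 18 (adjusted p = 6.42e-07) and of helper lineage genes 2 of 12 (adjusted p = 0.00126). Prf1 rose by 2.04 ± 0.26, Cdkn1a, which encodes the cell cycle inhibitor p21, by 1.99 ± 0.35 and Glipr1 by 1.09 ± 0.15. Dapl1, Klf3 and Irf7 fell by 5.03 ± 0.67, 6.81 ± 0.84 and 1.43 ± 0.25, and Plaur was at least 217-fold lower. Type I interferon response (0.307), glycolysis (0.307), oxidative phosphorylation (0.307) and cytotoxic effector (0.454) lost their calls with an estimated correlation. In all 8 genes rose and 147 fell, against 66 and 322 with DESeq2. The count of 155 became 51, 117 and 47 without replicate 1, 2 or 3, 47 without the batch term and 238 with the set as replicate block.

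Between the ends of this series, DP and NEG cells, 16 of 18 memory and stem-like genes fell (adjusted p = 4.2e-15, and 0.00604 with an estimated correlation), with Satb1 at -6.47 ± 0.58, Klf2 at -6.33 ± 0.72 and Lef1 at -4.33 ± 0.78. So did 15 of 16 resting Treg genes (adjusted p = 4.2e-15). Exhaustion regulators rose in 10 of 15 genes, with Nr4a2 at 3.60 ± 0.39 and Tox at 2.83 ± 0.35. Of the inhibitory receptors 7 of 12 rose and 2 fell, with Pdcd1 at 5.76 ± 0.89 and Lag3 at 5.55 ± 0.95, and of the cytotoxic effector list 11 of 20 rose, with Prf1 at 3.05 ± 0.27. The glycolysis list rose in 14 of 18 genes, oxidative phosphorylation in 13 of 22 and proliferation in 10 of 20, or 18 adjusted over the list alone. With an estimated correlation these 6 lists, in this order, had adjusted p of 0.133, 0.261, 0.261, 0.187, 0.253 and 0.277. Genes of the type I interferon response fell in 14 of 22 cases (adjusted p = 1.21e-07, and 0.27 with an estimated correlation), with Irf7 at -2.17 ± 0.26. The summed proliferation genes stood at 1600 ± 1130 CPM in NEG and 7550 ± 1730 in DP cells. Igfbp7, Rgs8, Dusp14 and Csf1 were at least 2130-fold, 1180-fold, 1170-fold and 1020-fold higher, and Ifngr2, the interferon-gamma receptor chain, and Tmem108 at least 1600-fold and 1140-fold lower. In all 2202 genes rose and 2045 fell. The count of 4247 became 2904, 3040 and 2309 without replicate 1, 2 or 3 and 1794 without the batch term, and 15 of the 20 genes named by the rule passed in every leave-out fit.

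In DP cells the genotypes were compared with yfp. Memory and stem-like genes were higher as a list in DKO DP cells, with a median of 1.76 (adjusted p = 1.06e-09, and 0.022 with an estimated correlation), and 0 members passed singly, over all genes or adjusted over the list alone. Tcf7 averaged 15.6 ± 14.6 CPM in DKO (n = 4) and 0.905 ± 0.895 in yfp DP cells (n = 3), Id3 4.50 ± 1.20 and 0.361 ± 0.554, and Slamf6 82 ± 20.7 and 18.8 ± 17.6. Their edgeR changes were 4.39 ± 1.75, 4.05 ± 1.94 and 1.98 ± 0.58. Summed CD4 T cell markers were 45.6 ± 31.6 CPM beside 13.7 ± 5.14, and B cell markers 7.99 ± 8.84 beside 0.938 ± 0.841, higher in each DKO than in each yfp library. In DKO DP cells immediate early AP-1 (0.188), the NF-kB and TNFR family (0.26), resting Treg (0.076), helper lineage (0.188) and CD4 T cell markers (0.188) lost their calls with an estimated correlation. The memory and stem-like list had a median of 1.03 in Il10 DP cells (adjusted p = 9.33e-05, and 0.109 with an estimated correlation) and 0.87 in Ebi3L DP cells (adjusted p = 0.0366, and 0.318). In Ebi3L DP cells the type I interferon response list had a median of -0.96 (adjusted p = 5.13e-07, and 0.318). edgeR called 0 of 12943 genes for DKO, Il10 or Ebi3L, with 680, 156 and 722 at an unadjusted p under 0.05, and DESeq2 called 127, 38 and 112. Limma on the deposited values called 1 gene for DKO and 2 for Ebi3L.

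**Figure D4:**
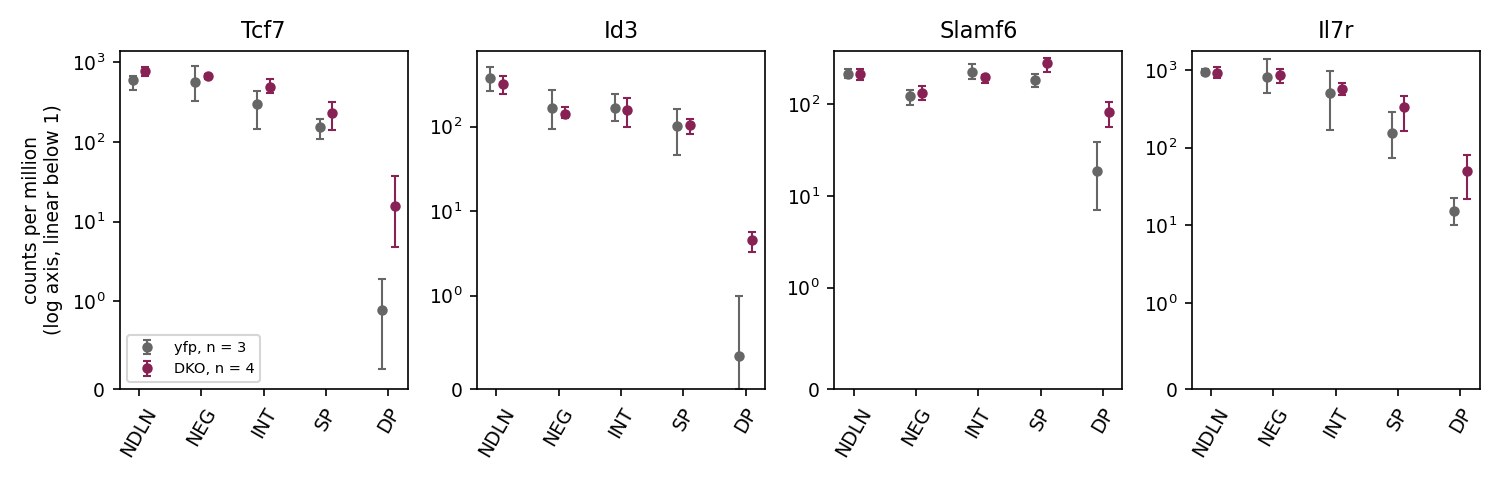
Mean level of Tcf7, Id3, Slamf6 and Il7r in CPM in each CD8 population of yfp (3 libraries) and DKO (4 libraries), with the lowest and highest library as bars, on an axis that is linear below 1 CPM and logarithmic above. In DP cells Tcf7 averaged 0.905 CPM in yfp and 15.6 in DKO.

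In SP cells, helper lineage genes were higher in DKO as a list, with a median of 1.02 (adjusted p = 2.42e-08, and 0.0185 with an estimated correlation) and 6 of 17 genes rising when adjusted over the list alone. Il2 stood at 5.05 ± 0.82 (adjusted p = 0.0859), Il21 at 3.26 ± 0.88, Ahr at 1.53 ± 0.49 and Gata3 at 0.79 ± 0.24. Summed CD4 T cell markers were 72.7 ± 26 CPM in DKO and 37.5 ± 16.2 in yfp. B cell markers were 24.2 ± 18 and 6.97 ± 3.43 and stromal markers 66.6 ± 27.3 and 33.7 ± 15. These unadjusted sums do not tell genotype from batch. Of the immediate early AP-1 list 7 genes rose adjusted over the list alone (adjusted p = 6.16e-11, and 0.135 with an estimated correlation), of the memory and stem-like list 7 (adjusted p = 3.16e-09, and 0.0866) and of the NF-kB and TNFR family 5 (adjusted p = 5.19e-08, and 0.116). In Ebi3L SP cells 7 of 22 type I interferon response genes fell when adjusted over the list alone (adjusted p = 4.1e-12, and 0.306 with an estimated correlation), with Usp18 at -1.65 ± 0.34. In Il10 SP cells 4 inhibitory receptors fell when adjusted over the list alone (adjusted p = 3.82e-07, and 0.199). edgeR called 0 of 13255 genes for DKO, Il10 or Ebi3L, with 973, 551 and 618 at an unadjusted p under 0.05, and DESeq2 called 171, 85 and 111. For DKO, 85 and 3 genes were called without DKO replicates 1 and 2, and 2 and 1 without yfp replicates 1 and 2. Limma on the deposited values called 7. Without the filter on low counts 259, 77 and 157 were called for DKO, Il10 and Ebi3L. For Ebi3L, 2 were called without yfp replicate 1 and 6 with the set as replicate block.

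In INT cells, type I interferon response genes were lower, in 11 of 22 cases adjusted over the list alone for DKO (median -0.68, adjusted p = 1.03e-15, and 0.676 with an estimated correlation) and in 10 for Ebi3L (median -0.79, adjusted p = 1.76e-16, and 0.395). Bst2, an interferon-induced membrane protein, stood at -0.72 ± 0.18 and -0.91 ± 0.18. Inhibitory receptors were called for Il10 (adjusted p = 0.0123, and 0.897 with an estimated correlation). edgeR called 1 of 12909 genes in each genotype, Rab4a, a small GTPase of endosomal recycling, at 3.21 ± 0.33 in DKO (adjusted p = 0.00298), 2.87 ± 0.35 in Il10 (adjusted p = 0.0276) and 2.79 ± 0.32 in Ebi3L (adjusted p = 0.0128), named after its values were seen. With a separate gene model overlapping it, counts at this locus may be shared. At an unadjusted p under 0.05 there were 735, 574 and 648 genes, and DESeq2 called 115, 112 and 123. The call was lost in all 3 genotypes without set 8 and with the set as replicate block, and for Il10 and Ebi3L also without the batch term, without batch 3 and by limma on the deposited values. The count for DKO was 0 without yfp replicate 1 and 4 without DKO replicate 4 or yfp replicate 2. For Il10 it was 1 without Il10 replicate 1 and 0 in the other leave-out fits, and for Ebi3L 1 without Ebi3L replicate 2, 8 without yfp replicate 2 and 0 in the others.

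In NEG cells edgeR called 0 of 12484 genes for DKO, Il10 or Ebi3L, with 354, 527 and 501 at an unadjusted p under 0.05 and 51, 101 and 78 by DESeq2. Immediate early AP-1 was called for DKO and Ebi3L and cytokine receptors and STAT3 targets for Il10, with adjusted p of 0.517, 0.523 and 0.176 with an estimated correlation. For Il10, 769 genes were called without Il10 replicate 2, which leaves 1 Il10 library, that of fewest detected genes in the series (10400), assumed to vary like the other groups, and for Ebi3L 1 without yfp replicate 2. Erythroid and platelet markers stood at 837 CPM in NEG Ebi3L replicate 2, against 2.1 and 0.54 in replicates 1 and 3. In NDLN cells proliferation genes fell in 9 of 20 cases for Il10 when adjusted over the list alone (median -2.59, adjusted p = 8.12e-18, and 0.469 with an estimated correlation). Ncapg, a condensin subunit of mitotic chromosomes, was the only one of 12336 genes called, at 0.0242 CPM in Il10 and 17.1 in yfp cells, and it passed among the leave-out fits only in that without yfp replicate 3. It was also lost without set 8 and with the set as replicate block. edgeR called 0 genes for DKO and Ebi3L in NDLN cells, with 526, 573 and 547 genes at an unadjusted p under 0.05 for DKO, Il10 and Ebi3L and 81, 107 and 80 by DESeq2. For DKO 1 gene was called without DKO replicate 2 or yfp replicate 1.

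The step from NEG to DP was compared between genotypes within sources. In DKO the memory and stem-like list had a median difference of 1.72 from yfp (adjusted p = 9.06e-11, and 0.00665 with an estimated correlation), and 4 of 18 genes were higher adjusted over the list alone. Slamf6 stood at 2.38 ± 0.55, Ccr7 at 3.15 ± 0.83, Tcf7 at 3.66 ± 1.40 and Il7r at 1.35 ± 0.44. edgeR called 0 of 13788 genes for DKO, Il10 or Ebi3L, with 430, 681 and 480 at an unadjusted p under 0.05 and 13, 58 and 20 by DESeq2, and limma on the deposited values called 2 for Ebi3L. For Il10, 729 were called without Il10 replicate 2, which leaves 1 source with the NEG library of fewest detected genes, and 1 without yfp replicate 2.

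Counts summed over the 5 populations of each source, a comparison chosen after seeing the data, gave 11 genes for DKO, 2 for Ebi3L and 0 for Il10 among 14861, with 784, 867 and 494 at an unadjusted p under 0.05. In DKO Rab4a rose by 2.53 ± 0.28 and Sytl1 by 1.87 ± 0.20 (adjusted p = 0.0058 each), and Map3k8, a kinase downstream of TNF receptors, by 0.82 ± 0.12. Serpina3f and Serpina3g fell by 1.87 ± 0.27 and 1.07 ± 0.15 and Cd244 by 1.43 ± 0.22 in DKO. Without the batch term 2 and 0 genes were called for DKO and Ebi3L. For DKO the count was 2 without DKO replicate 1, 3 without DKO replicate 3, 2 without DKO replicate 4, 1 and 0 without yfp replicates 1 and 2, and 2 without yfp replicate 3. For Ebi3L it was 0 without Ebi3L replicate 1, Ebi3L replicate 3 or yfp replicate 3, 1 without Ebi3L replicate 2 or yfp replicate 1 and 8 without yfp replicate 2.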

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

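Of the tests here, the thinning to equal depth and the other splits of the libraries were set before their results were seen, and the remaining tests of explanations were chosen after it. Of the 579 genes past the test of the site difference for IL10 against DN Tregs, 539 had a smaller fold change in the tumour than in the lymph node and 40 a larger one. These were 189 and 19 of 208 for Ebi3 against DN and 15 and 8 of 23 for IL10 against Ebi3. These stand out because the effect of one contrast differed between sites. For IL10 against DN the site difference was -3.61 for Itgae, -3.77 for Fgl2, -2.18 for Icos, -2.98 for Maf, -2.80 for Prdm1, 5.28 for Ly6c1 and 3.09 for Satb1. For Ebi3 against DN it was -2.88 for Itgae, -1.77 for Fgl2, -1.84 for Icos, 4.18 for Ly6c1, -2.08 for Cd40lg and -1.39 for Slamf6, and for IL10 against Ebi3 -2.01 for Fgl2, 2.42 for Themis, 1.84 for Gpr18 and 2.46 for Asap1.

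Depth is argued against as the whole cause of smaller tumour differences, as are IL10 cells in the DN sort for IL10 against DN. With every Treg library thinned to 9.73 M counts, 592 genes passed for IL10 against DN, 553 of them smaller in the tumour. If IL10 cells in the DN sort made the effector genes alike, Il10 would reach their share, but the highest tumour DN library held 2.57% of the mean Il10 level of tumour IL10 Tregs. The 18 effector genes lower in this test stood at a lower quartile of 56.8% and a median of 69% of their IL10 level in tumour DN Tregs, and at a median of 14.1% in the lymph node. Levels moved in both groups, since Fgl2 stood at 8.25 CPM in lymph node and 296 in tumour DN Tregs, and Itgae at 851 in lymph node and 161 in tumour IL10 Tregs. Other mixed sorts and the site stay open and untested.

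Memory and stem-like genes stood higher in DKO than in yfp DP cells. Their DKO and yfp steps from NEG to DP differed (adjusted p = 0.00665 with an estimated correlation). At the preset correlation one library is argued against, since the highest adjusted p over 7 leave-out fits was 1.55e-06, without DKO replicate 4. Within batch 1 alone the list stood at a median of 1.73 with 16 of 18 genes above 0. Its adjusted p of 7.44e-07 became 0.312 with an estimated correlation, so batch stays open. The 143 genes lower in yfp DP than SP cells gained a lower quartile of 4.77% of SP levels in DKO DP cells. Tcf7 gained 6.39% and Slamf6 22.4%. Picking genes low in yfp DP favours gains, so this decides nothing. CD4 T or B cells, with markers higher in DKO, stay open and untested beside SP cells in the DP sort and genotype. Havcr2 stood at -0.29 ± 0.20.

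Ebi3 stood lower in DP, SP and INT cells of DKO and Ebi3L. Batch or set is argued against, since 12 of 12 pairs of these cells sharing set and batch label were lower. Separation over sources had fixed the DP and SP pairs, and all come from 4 source pairs. In set 12, of differing batch labels, 2 of 3 were lower. Tregs in the CD8 sort, from the Foxp3 and Folr4 levels of the yfp SP libraries and the highest Ebi3 level of a Treg library, 15.7 CPM, could bring at most 23.7, 9.75 and 3.51% of Ebi3 in yfp replicates 1, 2 and 3. The first is above the share of 10% set as a bound, but it rests on Folr4 alone, at 45.6 CPM against 278 in the lowest Treg library. Foxp3 stood at 0 in that library, against at least 29.1 in Tregs, so the markers disagree, the bound crosses kit versions, and Tregs stay open as a source of part of it. Expression of Ebi3 by the CD8 cells themselves, lost with the genotype, was not tested and stays open.

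The next values each lay far from the other 3 libraries of a DKO group, in 7 of 44 tests over 5 groups, where chance flags about 5%. Il10 stood at 53.4 CPM in DP DKO replicate 3, against 0.102 to 4.01, and at 2.80 CPM in INT DKO replicate 4, against 0.15 to 0.256. CD4 T cell markers stood at 92.8 CPM in DP DKO replicate 3, against 28 to 32.4. Pdcd1 stood at 42.2 CPM in NDLN DKO replicate 2, against 6.51 to 10.9. In NEG DKO replicate 1 Ebi3 stood at 0.428 CPM, against 0 to 0.0427, and myeloid markers at 104, against 137 to 139. SP DKO replicate 4 held 28.5 M counts, against 23.7 to 24.5 M.

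Other splits of the same libraries were counted for each comparison of 3 or more libraries. With 3 against 3 there are 10 splits, too few for a share under 0.05, and the real split alone, 1 of 10, gave as many genes in every Treg contrast and yfp population contrast. In the Treg contrasts the 3 other splits that part each batch pair, as the real one does, gave at most 29 genes, and the splits that keep a pair together at most 84. The highest other split gave 84 genes for naive IL10 against DN (2301 in the real split), 29 for naive DN Tregs against Teff (1575), 44 for NEG against NDLN (200) and 1 for INT against NEG (120). It gave 1 for IL10 against DN in tumour (108) and lymph node (2088) and for DN Tregs across sites (3017). It gave 0 for SP against INT (626), DP against SP (155), DP against NEG (4247), the other Treg contrasts (92, 366, 1203, 1323, 1681, 654, 1658 and 707) and the Treg site differences, whose real splits gave 657, 477 and 85 in a fit of the libraries concerned. Every split reaches a real count of 0, so the 35 of 35 splits for DKO against yfp in DP, SP, NEG and NDLN and in the DP against NEG difference say nothing about chance (highest other 1, 335, 2, 3 and 0). In INT 6 of 35 gave as many as the real 1 (highest other 22), so chance cannot be excluded there. The 335 genes in SP came from DKO replicate 1 with the 3 yfp libraries against the other DKO libraries, which points to a structure of the samples. The same holds for the 10 of 10 splits for Ebi3L against yfp in DP, SP, NEG, NDLN and the DP against NEG difference, with a real 0 (highest other 3253, 2983, 2072, 2697 and 0). In INT 4 of 10, too few splits for a share under 0.05, gave as many as the real 1 (3345). The split that follows batch, Ebi3L replicate 1 with yfp replicates 1 and 2 against the rest, gave these highest counts except in the difference, and with the set as replicate block Ebi3L gave 1, 6, 0, 0 and 1 genes in DP, SP, INT, NEG and NDLN.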

How the results depend on the processing

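The processing section names alternatives chosen after seeing the data. The cause of a changed count was not tested except where fewer libraries were fitted. Single genes kept their direction and side of the threshold in 14507 of 17657 alternatives for 1967 results, 3141 became weaker, 7 stronger and 2 reversed. Both reversals came with limma on the deposited values, Marcks in tumour against lymph node IL10 Tregs at 0.06 and Selp in naive IL10 against DN Tregs at 0.116. At the preset correlation lists kept their call in 1800 of 1901 alternatives for 269 results and weakened in 101. The estimated one lost many calls. A count of 0 does not exclude changed genes. In simulated DKO against yfp DP libraries 20% of 2-fold and 50% of 4-fold changes were recovered.

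Without each replicate in turn the lowest and highest counts were as follows. Tumour IL10 against DN Tregs gave 32 and 45, Ebi3 against DN 10 and 28 and IL10 against Ebi3 32 and 121, and lymph node Tregs 1126 and 1430, 765 and 1029, and 178 and 450 in this order. Naive Tregs gave 1241 and 1550, 796 and 1060, and 278 and 498, DN Tregs against Teff 850 and 1123, and tumour against lymph node 1731 and 2242 for DN, 535 and 801 for IL10 and 691 and 887 for Ebi3 Tregs. The site differences gave 211 and 338 for IL10 against DN, 52 and 102 for Ebi3 against DN and 7 and 12 for IL10 against Ebi3. In yfp cells NEG against NDLN gave 26 and 763, INT against NEG 1 and 19, SP against INT 80 and 301, DP against SP 47 and 117 and DP against NEG 2309 and 3040. Genotype counts ran from 0 to 85 for SP DKO, 2 for SP Ebi3L, 4 for INT DKO, 1 for INT Il10, 8 for INT Ebi3L, 769 for NEG Il10, 1 for NEG Ebi3L, NDLN DKO and NDLN Il10, and 729 for the Il10 difference of DP against NEG. Source sums ran from 0 to 10 for DKO, 1 for Il10 and 8 for Ebi3L. Each of the other genotype comparisons gave 0 throughout.

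With no replicate block, that is without batch in the fit, tumour Tregs gave 33, 16 and 51 genes for IL10 against DN, Ebi3 against DN and IL10 against Ebi3, lymph node Tregs 1115, 762 and 250, naive Tregs 1374, 899 and 322 and the site differences 170, 40 and 7. It gave 857 for DN Tregs against Teff, 1849, 643 and 753 for tumour against lymph node DN, IL10 and Ebi3 Tregs, 53 for NEG against NDLN, 4 for INT against NEG, 9 for SP against INT, 47 for DP against SP and 1794 for DP against NEG. It gave 2 for SP DKO, 0 for INT Il10 and INT Ebi3L, and 2 and 0 for DKO and Ebi3L source sums. The set as replicate block gave 238 for DP against SP, 1018 for SP against INT, 1 for DP Ebi3L and NDLN Ebi3L, 6 for SP Ebi3L and 0 for NDLN Il10 and the 3 INT genotypes, and it changed no other count by over 1.5 times.

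DESeq2 gave 221, 196 and 637 genes in the tumour contrasts of IL10 against DN, Ebi3 against DN and IL10 against Ebi3 Tregs and 906, 404 and 84 for their site differences, 706 for NEG against NDLN, 545 for INT against NEG, 1356 for SP against INT and 388 for DP against SP. For DKO, Il10 and Ebi3L it gave 127, 38 and 112 in DP, 171, 85 and 111 in SP, 115, 112 and 123 in INT, 51, 101 and 78 in NEG, 81, 107 and 80 in NDLN and 13, 58 and 20 for DP against NEG. No filter on low counts gave 4 for DP DKO, 9 for DP Ebi3L, 259, 77 and 157 in SP, 122, 64 and 161 in INT, 32, 98 and 37 in NEG, 22, 42 and 11 in NDLN and 187 for INT against NEG. DESeq2 size factors in edgeR gave 1 for the Ebi3L difference of DP against NEG. limma on the deposited values gave 181, 147 and 675 in the tumour contrasts, 1956 for tumour against lymph node IL10 Tregs, 996 for SP against INT, 1 for DP DKO, 2 for DP Ebi3L and the Ebi3L difference, 7 for SP DKO, 3 for INT DKO and 0 for INT Il10 and INT Ebi3L. Without batch 3 DP DKO gave 2 and INT Il10 and INT Ebi3L 0. Without set 8 the INT genotypes and NDLN Il10 gave 0, SP DKO 4 and SP Ebi3L 2. Without the Ebi3 library high in Lyz2 lymph node Ebi3 against DN gave 1060, IL10 against Ebi3 351, and their site differences 129 and 15. Counts of the remaining alternatives stayed within 1.5 times.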

Other observations

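The values here were read after the comparisons were seen and carry no test of their own beyond those given above. In yfp cells summed proliferation genes stood at 764 ± 311 CPM in NDLN, 1600 ± 1130 in NEG, 2590 ± 1140 in INT, 5140 ± 1370 in SP and 7550 ± 1730 in DP cells (SD, n = 3), and summed NK cell markers at 123 ± 20.7, 387 ± 203, 719 ± 139, 1030 ± 135 and 843 ± 74.

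Rab4a stood at 0.478 to 13 CPM in the 15 yfp libraries of the CD8 series, with a median of 4.37, and at 2.4 to 48.5 CPM in the 45 knockout libraries, with a median of 29.2. In libraries sharing set and batch label it was higher in the knockout in 9 of 10 pairs, from 2 pairs of sources, and in 4 of 5 pairs of set 12, whose batch labels differ. Of the 16 tested genes within 500 kb of Rab4a, 0 passed in the DKO against yfp edgeR fit of counts summed per source. The smallest adjusted p was 0.946.

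Xist, the transcript of the inactive X chromosome, stood at 407 to 657 CPM and the Y-linked Ddx3y at 0 in the 10 libraries of set 8, which holds yfp replicate 1 and DKO replicate 1. In the other 50 CD8 libraries Ddx3y stood at 73.9 to 329 CPM, and in the Treg series Xist at 220 to 405 CPM. Set 8 holds no Il10 or Ebi3L library, so this difference is unbalanced in their comparisons with yfp, and fits without it are given above.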
